A study of Homo sapiens with 40 samples.

How the data were processed

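RNA was sequenced from 40 libraries of MCF7, an established human breast carcinoma line with a luminal, estrogen receptor positive phenotype. Per the labels, a pair of derived lines was compared. Each carried the endogenous p53 gene together with an added p53, either wild type (WT) or a form called 2KR. Cells of each line were taken untreated (0 h) and at each hour from 1 to 9 h after 10 Gy of X-rays, with 2 libraries per line and hour, which gives 20 groups. Per the labels' protocols, polyadenylated RNA was captured from 500 ng of RNA, libraries were strand-specific, and all were read on 1 lane as paired reads of 100 bp. Polyadenylated capture under-represents replication-dependent histone transcripts. The labels give no harvest date or culture of origin for a library.

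The deposited values were of 2 kinds. The authors' estimated counts per gene were made with salmon, which the names of the deposited tables state, and were given as whole numbers without further scaling. The authors' TPM values came from the same tool and add up to the same total in every library. The submitters' processing notes name the genome build hg38. The salmon version, its settings, the transcript annotation used and the way transcripts were added up to genes are not given in the sources used here. Because salmon shares reads among similar transcripts by estimation, values of near-identical genes (the MT-ND1 pseudogene MTND1P23, FAM72D and its copies, the ribosomal RNA genes) are uncertain. Reads of the added p53 and of the endogenous gene both count as TP53, so the lines' TP53 values hold their sum. All 58735 gene identifiers matched GENCODE release 29 on GRCh38, which gave symbols, types and coordinates. Every column of the deposited tables matched a library's label.

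Total counts per library ran from 10583410 to 32447454 with a median of 25763000. Mitochondrial genes took 3.58% to 31.7% of a library's counts, so the depth left for other genes varied more than the totals did. Levels are given as CPM, with TMM scaling where a level of a gene is compared between libraries. Libraries were checked by total count, share of mitochondrial counts, share of the 10 most abundant genes and Pearson correlation of log2(CPM + 0.5) with every other library. Replicates were compared by a chi-square test over genes with at least 20 counts per pair; chi-square per degree of freedom was between 4.8 and 523, so no library looked like a copy of its partner.

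Counts, which were already whole, were tested with edgeR 4.0.16 in R 4.3.3. Genes with enough counts by edgeR's filterByExpr were kept (18830), libraries were scaled by TMM, and a model with a mean for each of the 20 groups was fitted over all 40 libraries by quasi-likelihood, with 20 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene was called at an adjusted p under 0.05. Each line was compared with its own 0 h libraries over an early (1 to 3 h), a middle (4 to 6 h) and a late (7 to 9 h) window, using the mean log2 level of the 6 libraries of a window. The other comparisons were 2KR against WT at 0 h, the difference between the lines' responses in each window, late against early in each line with its difference between lines, and F tests over all 9 hours. That made 16 comparisons. Log2 changes are given with their standard error (SE), which was computed from the log2 change and the quasi-likelihood F statistic. The windows follow the known spacing of p53 pulses after ionizing radiation.

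For gene groups, 22 lists were fixed: p53 targets of arrest, apoptosis, repair, feedback and metabolism, a core of p53 targets common to published screens, G2 and mitosis, G1/S and replication, replication-dependent histones, NF-kB targets, interferon-stimulated genes, immediate early genes, ATF4 and endoplasmic reticulum stress genes, estrogen receptor targets, cholesterol synthesis, heat shock, hypoxia and glycolysis, acetyltransferases and deacetylases with TP53, luminal markers, basal and mesenchymal markers, blood cell markers, and mitochondrially encoded genes as a sign of RNA quality. All 338 distinct list genes matched an identifier. Each list was tested with camera (limma 3.58.1, correlation 0.01) on voom values, and p-values were adjusted over the 286 tests of 22 lists in 13 comparisons. Camera was repeated with the correlation estimated from the data, and the rotation test fry was also run.

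Genes are named by a rule: TP53 and members of the lists; for each window response, for 0 h, for late against early and for each difference, the 8 called genes with the highest and the 8 with the lowest log2 change among genes with a symbol and a mean of at least 5 CPM; and for each F test the 8 genes with the smallest p-value. For comparisons within a line or at 0 h, every library of one side also had to lie above or below every library of the other. Any gene named outside this rule is said to be chosen after its values were seen.

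The groups, windows, lists, tests, naming rule and most alternatives were set before the data were examined. The alternatives were DESeq2 1.42.0, limma voom, DESeq2 size factors in edgeR, library totals alone, no filter, a mean of at least 5 CPM, limma on log2(TPM + 1) and log2(TPM + 0.1), the replicate number as a block over all libraries or within each line, windows of 2 hours (2 to 3, 5 to 6 and 8 to 9 h), the libraries of one line alone, and leaving out each library in turn. Added after seeing the data were a fit to 35 libraries, without the untreated 2KR replicate 2 and all 1 h libraries, voom with library quality weights, and a comparison of the lines over hours 2 to 9. In the 35 libraries the early window covers 2 to 3 h and the untreated 2KR group holds 1 library, which is assumed to vary like the other groups. A fit to 39 libraries left out the untreated 2KR replicate 2 alone.

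The edgeR step was tested on simulated data for 18830 genes with the spread found in the 35 libraries, and with 100 genes changed 1.5-fold and 100 changed 2-fold in the late window of the 2KR line. It recovered 86% and 96% of them in the 2KR late response, 63% and 94% in the late difference between lines, 100% of each in late against early in 2KR, and 86% and 98% in its difference between lines, with 8 to 14 false calls per comparison. The simulation held all 40 libraries, with 2 untreated 2KR libraries. Common dispersion, edgeR's measure of spread, was 0.0102 in the 35 libraries and 0.0520 with all 40. The rates therefore describe neither the fit to 40 libraries nor that to 35, which has 1 untreated 2KR library. Results for 1 gene among those with the leading values are not reported here.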

Results

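RNA-seq profiles were collected from MCF7 breast carcinoma cells that carried their endogenous p53 gene together with an added wild-type p53 (WT) or an added p53 form called 2KR. Each line was profiled untreated (0 h) and at every hour from 1 to 9 h after 10 Gy of X-rays, with 2 libraries per line and hour, 40 libraries in all. The question behind the series is how gene expression over time depends on p53 and its acetylation. Total counts per library ran from 17687665 to 29361982 in the 20 WT libraries. In the 2KR line they ran from 19923773 to 32447454 at hours 2 to 9, and the 0 h and 1 h libraries held 24616093, 10583410, 21834830 and 24256241. A total of 18830 genes was tested. The labels do not say that replicates came from separate cultures, so the p-values measure the spread between these libraries, which may be technical. Values for a window compare its 6 libraries with the 2 untreated libraries of the same line, and each ± is a standard error unless said otherwise.

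The untreated 2KR replicate 2 stood apart from every other library. Mitochondrial genes took 31.7% of its counts, against 3.58% to 13.3% in the other 39 libraries, and the nuclear non-coding RNA MALAT1 (ENSG00000251562, GRCh38 chromosome 11, 65497688 to 65506516) reached 13691 CPM, against 397 to 2329 elsewhere. Its median correlation with the other libraries was 0.729, against 0.896 to 0.978 for the rest. The standard deviation of log2 ratios between the replicates was 1.34 for 2KR at 0 h and 0.72 for 2KR at 1 h, and at most 0.28 in the other groups. The 1 h 2KR replicate 1 had 13.3% mitochondrial counts. The 1 h 2KR replicate 2 lay nearest to the untreated 2KR replicate 1 (r = 0.994, with a standard deviation of log2 ratios of 0.181), and the untreated replicate 2 nearest to the 1 h replicate 1 (r = 0.868). The labels were kept as deposited, and untreated 2KR values rest on them. From 2 h on, mitochondrial genes took 5.78% to 8.78% of 2KR counts, against 3.58% to 8.31% in all WT libraries. Comparisons that use the untreated 2KR libraries rest on this pair, so counts of genes are also given for 35 libraries, without the untreated 2KR replicate 2 and the 1 h libraries of both lines.

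**Figure D1:**
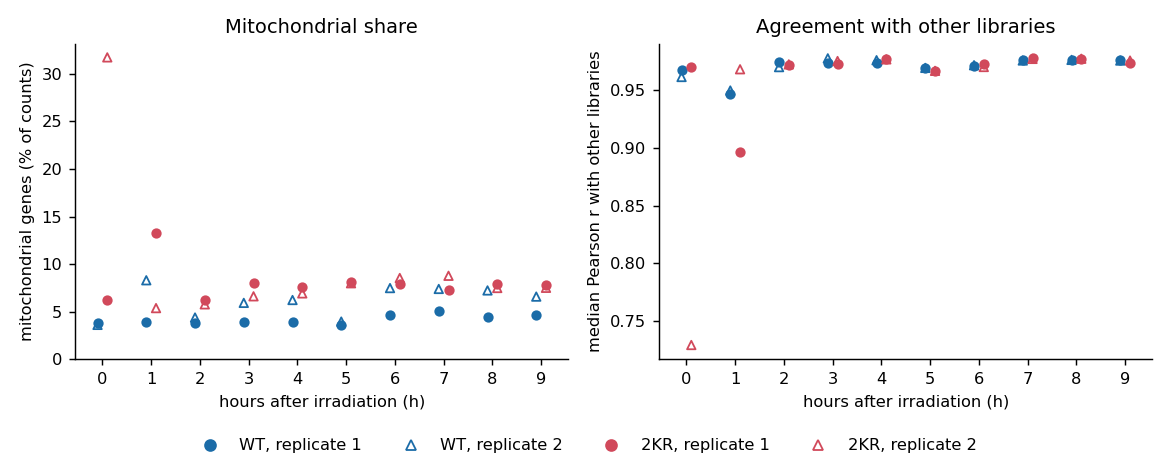
Share of counts from mitochondrial genes (percent) and median Pearson correlation with the other 39 libraries, by hour after irradiation, for each library of the WT and 2KR lines. The untreated 2KR replicate 2 sits at 31.7% and a median correlation of 0.729, apart from all others.

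TP53 (ENSG00000141510, GRCh38 chromosome 17, 7661779 to 7687550), which encodes p53, was higher in the 2KR line at every hour. Its level was 188 ± 10.7 CPM in WT (SD, n = 20 libraries, range 172 to 214) and 312 ± 26.5 CPM in 2KR (SD, n = 20 libraries, range 272 to 359), with no overlap. At 0 h the difference was 0.89 ± 0.10 on the log2 scale (edgeR, adjusted p = 1.16e-05). Reads of the added and the endogenous gene are summed in these values. TP53 did not pass the test in any WT window, with log2 changes of 0.02 ± 0.08, -0.05 ± 0.08 and -0.10 ± 0.08. In 2KR it had -0.14 ± 0.08 early (not called), -0.24 ± 0.08 in the middle window (edgeR adjusted p = 0.0296) and -0.30 ± 0.08 late (0.00711). These calls were lost with library totals alone (-0.01 and -0.07), and the sign turned on log2(TPM + 1) (0.36 and 0.30, neither called). The middle call also ended without the untreated 2KR replicate 2, 2KR 4 h or 5 h replicate 2 or 2KR 6 h replicate 1 (adjusted p = 0.056 to 0.134).

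Before irradiation, the 2KR line expressed EPHA3, an ephrin receptor, far below WT (log2 -4.36 ± 0.45), together with IGF2BP2, an RNA-binding protein (-2.32 ± 0.22), the growth factor gene TGFB2 (-2.75 ± 0.73), the matrix protease gene MMP16 (-2.61 ± 0.44), and CPE, UGT1A6, HMCN1 and B3GALT5. These 8 genes were also called in the 35 libraries, where EPHA3 (ENSG00000044524, GRCh38 chromosome 3, 89107524 to 89482134) differed by -3.92 ± 0.31. Of the 8 genes with the highest values in 2KR, only SERPINF1, a secreted inhibitor of angiogenesis, was still called in the 35 libraries (2.91 ± 0.58 against 1.22). The others were MT-ND6, MT-ND4, MT-ND1, MT-ATP6, ANKRD20A11P, RNA5-8SN4 and PCLO, with values from 2.94 to 3.22. All 13 mitochondrially encoded genes were higher in 2KR at 0 h (median 2.81; camera adjusted p = 5.35e-12, and adjusted p = 0.205 with an estimated correlation), and 0 of 13 were called in the 35 libraries. Of the p53 targets, MDM2 (1.46 ± 0.35), GADD45A (1.70 ± 0.45) and DDB2 (0.93 ± 0.30) were higher with all libraries, against 0.00 ± 0.08, 0.27 ± 0.15 and -0.18 ± 0.12 in the 35, none of these called. With the 35 libraries, 6 of 17 estrogen receptor targets were higher in 2KR, among them RET (1.30 ± 0.09), PGR (0.83 ± 0.11) and TFF1 (0.51 ± 0.08), with camera adjusted p = 2.70e-05 and 0.00855 with an estimated correlation. There, 6 of 16 immediate early genes were lower, among them KLF6 (-1.07 ± 0.15) and IER3 (-0.96 ± 0.08), with camera adjusted p = 4.61e-07 and 0.0253 with an estimated correlation. The untreated 2KR group is 1 library there. With all libraries neither list was called (camera adjusted p = 0.772 and 0.157), and KLF6 had -0.60 ± 0.20, IER3 0.59 ± 0.43, RET 0.99 ± 0.15, TFF1 0.77 ± 0.16 and PGR 0.00 ± 0.48. The immediate early list had median levels of -0.10 and 0.36 in the untreated 2KR replicates 1 and 2, against 0.35 and 0.38 in WT, and the estrogen receptor list 0.37 and -0.76, against 0.29 and 0.13. Over all libraries edgeR called 4023 genes, 2736 higher and 1287 lower in 2KR, against 568 and 599 in the 35 libraries, with 612 shared. Without WT 0 h replicate 1 or 2 it called 877 or 819, and without 2KR 0 h replicate 1 or 2, 11410 or 390. MDM2, GADD45A, DDB2, PCLO and RNA5-8SN4 were not called without either WT replicate, nor TGFB2 and ANKRD20A11P without WT replicate 1. Without 2KR replicate 2, TGFB2 and the 8 highest genes, SERPINF1 included, were not called. Line and clone cannot be told apart in this design.

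A comparison of the lines over hours 2 to 9, added after the libraries were examined, set 16 libraries per line against each other and no untreated one. Its spread was estimated over the 35 libraries. Genes named here and not at 0 h were chosen after their values were seen. EPHA3 (-3.79 ± 0.08), IGF2BP2 (-2.64 ± 0.06), MMP16 (-2.26 ± 0.12), TGFB2 (-2.06 ± 0.11) and CPE were again lower in 2KR, as were LNCAROD, SCIN, a regulator of actin, and the transcription factor gene TFAP2A. COL12A1, a collagen gene (3.10 ± 0.13), the coagulation factor gene F5 (2.10 ± 0.11), the nuclear receptor gene PPARG (1.75 ± 0.04) and CTSD, cathepsin D (1.52 ± 0.02), were among those higher in 2KR, next to DNALI1, FLRT3, IFITM10, NTN4 and IGSF1. EdgeR called 3706 genes higher and 4040 lower, 545 of them at least 2-fold apart. Of the 1167 genes called at 0 h in the 35 libraries, 1080 were called here, 1076 with the same sign. Of the 4023 called at 0 h with all libraries, 2179 were called here, 2015 with the same sign.

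In the WT line, p53 target genes rose within the early window (1 to 3 h). Of 50 measured core p53 targets, 26 rose and none fell (median 0.91; camera adjusted p = 9.33e-118), or 39 adjusted over the list alone. The arrest genes BTG2, an antiproliferative factor (3.68 ± 0.29), GADD45A (2.97 ± 0.41) and CDKN1A, the CDK inhibitor p21 (2.74 ± 0.15), led the list of 11 arrest targets, 5 of which rose. Among apoptosis targets 9 of 17 rose, including BBC3, which encodes PUMA (2.52 ± 0.38), the death receptor gene FAS (2.38 ± 0.30) and the decoy receptor gene TNFRSF10C (2.21 ± 0.15). SESN1, a stress-induced regulator of mTORC1 (2.59 ± 0.12), led the metabolism list, where 7 of 14 rose. Among the 8 genes that limit p53, MDM2, its ubiquitin ligase (1.85 ± 0.32), the phosphatase gene PPM1D (1.56 ± 0.20) and CCNG1 (0.81 ± 0.13) rose. From the repair list XPC (1.12 ± 0.12) and POLH (1.00 ± 0.18) rose, 2 of 11. The zinc finger gene ZNF488 rose by 2.31 ± 0.16. Called decreases were smaller: CDCA2 (-0.71 ± 0.13), FAM72D, NAB2, HJURP, a centromere chaperone (-0.63 ± 0.10), ARSJ, ZNF324 and RIOX1. Of 30 G2 and mitosis genes 4 fell (11 adjusted over the list alone; median -0.45; camera adjusted p = 4.84e-24), while 0 of 30 G1/S genes were called. In total edgeR called 84 genes higher and 24 lower, against 629 and 469 in the 35 libraries, which held all 108. Without WT 0 h replicate 1 or 2 the count was 53 or 58, and without 2KR 0 h replicate 1 or 2, 256 or 255. MDM2, CDCA2, NAB2 and RIOX1 were not called without either WT replicate, nor were HJURP, ARSJ and ZNF324 without replicate 1 and FAM72D without replicate 2.

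CDKN1A (ENSG00000124762, GRCh38 chromosome 6, 36676460 to 36687339) went from 72.4 ± 2.12 CPM at 0 h to 1012 ± 101 at 3 h in WT (SD, n = 2 each), then 338 ± 4.47 at 7 h and 587 ± 2.57 at 9 h. In 2KR it went from 79.5 ± 8.45 CPM at 0 h to 1266 ± 32.7 at 3 h, 392 ± 1.43 at 7 h and 636 ± 39.4 at 9 h. MDM2 (ENSG00000135679, GRCh38 chromosome 12, 68808176 to 68850686) went from 258 ± 3.68 CPM at 0 h to 1786 ± 31 at 3 h, 412 ± 4.56 at 7 h and 966 ± 29.4 at 9 h in WT. The untreated 2KR libraries differed in MDM2, with 259 CPM in replicate 1 and 1166 in replicate 2, and the 3 h level was 2125 ± 103.

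**Figure D2:**
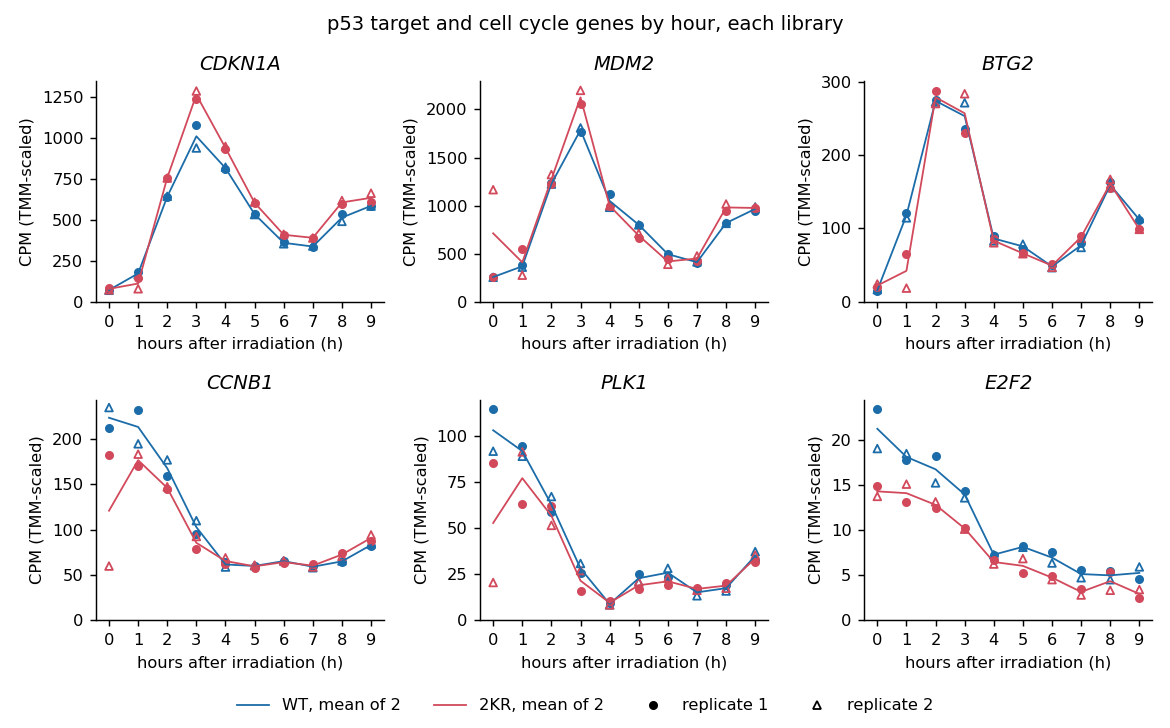
TMM-scaled CPM by hour after irradiation for CDKN1A, MDM2, BTG2, CCNB1, PLK1 and E2F2 in WT (blue) and 2KR (red). Lines join the means of 2 libraries, filled circles are replicate 1 and open triangles replicate 2. CDKN1A peaks in both lines at 3 h, at 1012 CPM in WT and 1266 in 2KR.

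In the middle window (4 to 6 h) the WT line combined high p53 targets with a fall of the mitotic genes. Core p53 targets rose in 39 of 50 cases (42 adjusted over the list alone; median 1.12; camera adjusted p = 1.20e-57). Among them were FAS (3.55 ± 0.32), CDKN1A (2.90 ± 0.15), MDM2 (1.53 ± 0.31) and FDXR, the mitochondrial ferredoxin reductase (1.95 ± 0.11). Repair targets rose in 6 of 11 cases, with RRM2B, a ribonucleotide reductase subunit (1.66 ± 0.43), XPC (1.64 ± 0.13) and DDB2 (1.51 ± 0.26). The highest changes outside the lists were in SMIM10L2A (4.19 ± 0.31), PLEKHG1, SERPINB5, which encodes maspin (3.68 ± 0.20), UBASH3B, EFCAB10, SLC52A1, a riboflavin transporter gene, and ANK1, all at least 3.18. Of 30 G2 and mitosis genes 28 fell (median -1.17; camera adjusted p = 1.43e-45). PLK1, the mitotic kinase (ENSG00000166851, GRCh38 chromosome 16, 23677656 to 23690367), stood at -2.57 ± 0.26 and CCNB1, cyclin B1 (ENSG00000134057, GRCh38 chromosome 5, 69167010 to 69178245), at -1.84 ± 0.19. KIF20A (-2.06 ± 0.12), CDC20 (-1.98 ± 0.12), HMMR (-1.92 ± 0.14) and CENPA (-1.78 ± 0.19) fell alongside. FJX1 and the transcription factor gene TFAP4 also fell. Of 30 G1/S genes 11 fell (17 adjusted over the list alone; median -0.43; camera adjusted p = 4.09e-11), but adjusted p = 0.0735 with an estimated correlation. Of the acetylation list, EP300 (0.75 ± 0.18) and CREBBP (0.89 ± 0.21), both acetyltransferase genes, rose and KMT5A, a histone methyltransferase gene, fell (-0.53 ± 0.15), with the list not called (camera adjusted p = 0.908). EdgeR called 630 genes higher and 696 lower, against 2304 and 2569 in the 35 libraries, which held all 1326. Without WT 0 h replicate 1 or 2 the count was 669 or 491, and without 2KR 0 h replicate 1 or 2, 2995 or 3054. MDM2 was not called without WT 0 h replicate 2.

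In the late window (7 to 9 h) the p53 targets stayed above the untreated level in WT while mitotic and replication genes lay below it. Core p53 targets were higher in 36 of 50 cases (41 adjusted over the list alone; median 1.01; camera adjusted p = 3.54e-53), among them FAS (2.91 ± 0.31), BTG2 (2.82 ± 0.27), CDKN1A (2.69 ± 0.15), TNFRSF10C (2.66 ± 0.16) and MDM2 (1.42 ± 0.31). SMIM10L2A, EFCAB10, SERPINB5 and PLEKHG1 were again among the highest, from 2.76 to 3.82. All 30 G2 and mitosis genes fell (median -1.22; camera adjusted p = 1.73e-54), including KIF20A (-2.37 ± 0.12), PLK1 (-2.29 ± 0.26), HMMR (-2.22 ± 0.14), CDC20 (-1.96 ± 0.12) and DLGAP5 (-1.76 ± 0.31), and so did DEPDC1 (-1.84 ± 0.37). G1/S genes fell in 18 of 30 cases (22 adjusted over the list alone; median -0.56; camera adjusted p = 2.29e-24), with E2F2 (ENSG00000007968, GRCh38 chromosome 1, 23506430 to 23531220) at -2.05 ± 0.15, the helicase subunit gene MCM6 at -1.33 ± 0.20 and E2F1 at -1.07 ± 0.10. Estrogen receptor targets fell in 6 of 17 cases (10 adjusted over the list alone; median -0.48; camera adjusted p = 3.42e-06, and 0.0326 with an estimated correlation), among them MYB (-0.86 ± 0.19), CXCL12 (-0.80 ± 0.23) and IGFBP4 (-0.74 ± 0.10). CTGF, a matricellular protein gene, had the lowest value (-2.68 ± 0.22), and 3 of 16 immediate early genes fell (EGR2, FOSB and EGR3; camera adjusted p = 0.00197, but adjusted p = 0.412 with an estimated correlation). EdgeR called 582 genes higher and 599 lower, against 2320 and 2685 in the 35 libraries, which held all 1181. Without WT 0 h replicate 1 or 2 the count was 616 or 432, and without 2KR 0 h replicate 1 or 2, 3020 or 3045. MDM2 and MYB were not called without either WT replicate, nor DEPDC1 without replicate 2.

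Of the remaining lists few members were called in WT in the late window. The single called members were MX1 of 16 interferon-stimulated genes (2.87 ± 0.46), HIST2H2BE of 16 histone genes (0.65 ± 0.20), FN1 of 7 basal and mesenchymal markers (0.89 ± 0.22), HSPE1 of 10 heat shock genes (-0.52 ± 0.13) and VEGFA of 12 hypoxia genes (-0.48 ± 0.15). Of 14 stress genes of the ATF4 list DDIT4 rose and 3 fell, including PSAT1 (-0.92 ± 0.13). None of 14 NF-kB targets, 14 cholesterol synthesis genes, 14 acetylation genes, 11 luminal markers, 3 blood cell markers or 13 mitochondrial genes was called by edgeR in that window. Camera's adjusted p lay between 0.0658 and 0.955 for these lists except the mitochondrial one (median 0.69, adjusted p = 0.0151, and adjusted p = 0.692 with an estimated correlation). Without replicate 2 of WT at 8 h or at 9 h, the mitochondrial list had 0.0727 or 0.0539. In the early window NF-kB targets (adjusted p = 0.00149) and ATF4 genes (0.00178) passed camera upwards, with adjusted p = 0.107 and adjusted p = 0.244 with an estimated correlation. Without WT 0 h replicate 1 the ATF4 list had 0.0718.

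The 2KR line also raised p53 targets in the early window, from untreated libraries that differed from each other. Core p53 targets rose in 40 of 50 cases and 1 fell (43 and 2 adjusted over the list alone; median 1.06; camera adjusted p = 5.43e-38). FAS rose by 2.91 ± 0.31, BTG2 by 2.71 ± 0.27, CDKN1A by 2.58 ± 0.15, SESN1 by 1.88 ± 0.12, PPM1D by 1.84 ± 0.20, the glutaminase gene GLS2 by 1.45 ± 0.27 and TRIAP1 by 1.26 ± 0.18. CDKN1A rose by 3.53 ± 0.08, BTG2 by 3.74 ± 0.13 and SESN1 by 2.80 ± 0.09 in the 35 libraries, where 44 of the 50 rose. MDM2 was not called with all libraries (0.54 ± 0.29), and rose by 2.68 ± 0.09 in the 35. EFCAB10, PRODH, a proline oxidase gene, C17orf82 and ZNF28 were among the other leading genes, of which ZNF28 was not called in the 35 libraries. The genes with the lowest values, GNRHR2 (-2.14 ± 0.32), the cohesin regulator gene PDS5B (-1.96 ± 0.26), ZNF605, FAM228B, MAB21L3, PPP1R3B, FOXP1 and RRP7BP, were not called in the 35 libraries, with values from -0.57 to -0.21 there. All 13 mitochondrial genes were lower (median -1.78; camera adjusted p = 5.54e-07, and adjusted p = 0.397 with an estimated correlation), against 0 in the 35 libraries (median 0.10). Without the untreated replicate 2 the mitochondrial list was not called (camera adjusted p = 0.207). Of 30 G2 and mitosis genes 10 fell (median -0.20; camera adjusted p = 0.0127, and adjusted p = 0.479 with an estimated correlation), against 18 in the 35 libraries (median -0.55). EdgeR called 942 genes higher and 3177 lower with all libraries and 324 and 240 in the 35, with 298 shared. Without 2KR 0 h replicate 1 or 2 the count of 4119 became 11592 or 149, and PRODH, ZNF28 and the 8 lowest genes were not called without replicate 2. Without replicate 1 the G2 and mitosis list was not called (camera adjusted p = 0.427).

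In the middle and late windows of the 2KR line, p53 targets were higher and mitotic genes lower than untreated. Core p53 targets rose in 37 cases and fell in 3 of 50 in the middle window (median 1.18; camera adjusted p = 2.90e-30), and rose in 40 and fell in 2 late (median 1.11; adjusted p = 1.07e-31). The 35 libraries had 43 and 44 rising. In the middle window SMIM10L2A (4.20 ± 0.32), SERPINB5 (4.05 ± 0.22), FAS (4.00 ± 0.33), UBASH3B (3.87 ± 0.39), PRODH, SLC52A1, EFCAB10 and TP53INP1, an autophagy and arrest gene (2.97 ± 0.23), led, and CDKN1A rose by 2.95 ± 0.15. Late, SPATA18, a regulator of mitochondrial quality (2.72 ± 0.22), and the mTORC1 inhibitor gene DDIT4 (2.64 ± 0.17) joined SMIM10L2A, FAS, SERPINB5, TP53INP1, EFCAB10 and CDKN1A (2.74 ± 0.15). G2 and mitosis genes fell in 22 of 30 cases in each of these windows (medians -0.78 and -0.82; camera adjusted p = 2.90e-16 and 1.92e-17), against 29 and 30 in the 35 libraries (medians -1.07 and -1.11). PLK1 stood at -1.78 ± 0.27 in the middle window and at -2.44 ± 0.17 in the 35 libraries. CCNB1 had -0.95 ± 0.20 in the middle window and -1.52 ± 0.08 in the 35 libraries. Without 2KR 0 h replicate 1, CCNB1 stood at 0.09 and was not called, nor was PLK1, and the G2 and mitosis list had adjusted p = 0.171 and 0.156. Among the lowest genes of the middle window, CD3EAP (-2.54 ± 0.19), KNOP1, the kinetochore gene CENPF (-2.13 ± 0.28), RGS16, GFOD1 and MXD3 were also called in the 35 libraries, while CHD7, a chromatin remodeler (-2.33 ± 0.36), and CAMK2N1 were not. Late, DMC1, the condensin gene SMC4, the kinetochore motor gene CENPE (-2.20 ± 0.24) and CREB3L1 were called in both, while IRX3 (-3.16 ± 0.43), EMC3-AS1, GNRHR2 and PDE3B were not called in the 35.

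G1/S genes fell in 14 of 30 cases late in 2KR and 1 rose (median -0.36; camera adjusted p = 2.59e-06, and adjusted p = 0.247 with an estimated correlation), with E2F2 at -2.06 ± 0.15 and MCM6 at -0.79 ± 0.20. Of the 30, 27 fell in the 35 libraries (median -0.67, adjusted p = 3.05e-05 with an estimated correlation), and MCM6 stood at -1.40 ± 0.06. Without the untreated 2KR replicate 1 the G1/S list lost its call and turned upwards (voom median 0.180; camera adjusted p = 0.690), and MCM6 was higher late (0.33; edgeR adjusted p = 0.00264). All 13 mitochondrial genes were lower in the middle and late windows (medians -1.71 and -1.78; camera adjusted p = 0.000152 and 7.59e-05, with adjusted p = 0.538 and adjusted p = 0.523 with an estimated correlation). The direction turned without the untreated 2KR replicate 2: in the 35 libraries the list lay above untreated (medians 0.34 and 0.25; camera adjusted p = 0.0588 and 0.114), and without that library alone it had adjusted p = 0.171 and 0.255, also upwards. Estrogen receptor targets fell in 11 of 17 cases late in the 35 libraries (median -0.43; camera adjusted p = 1.49e-07, and 0.00157 with an estimated correlation), and 5 fell with all libraries, IGFBP4 among them (-0.90 ± 0.10). EdgeR called 2204 genes higher and 4049 lower in the middle window and 2444 and 4078 late, against 1154 and 1570, and 1021 and 1370, in the 35 libraries. Shared calls numbered 1383 and 1302. Without 2KR 0 h replicate 1 or 2 the counts of 6253 and 6522 became 11827 or 1396 and 11919 or 1209.

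The test of the difference between the lines' responses called 0 genes early, 93 in the middle window and 661 late with edgeR and all libraries. At an unadjusted p under 0.05 the early test had 4182 genes. DESeq2 called 1573 genes early, limma voom 0, and limma on log2(TPM + 1) 2. Nearly all calls had a lower value in 2KR, 90 of 93 and 634 of 661. Among them were SRGAP1, a regulator of cell migration (-3.62 ± 0.73 in the middle window), the trafficking gene VPS35L (-3.32 ± 0.72), ZNF431 (-3.08 ± 0.66) and the anchoring protein gene AKAP13 (-2.98 ± 0.66), and late the nuclear RNA MALAT1 (-3.42 ± 0.90) and the mitochondrial pseudogene MTND1P23 (-3.61 ± 0.88). Without the untreated 2KR replicate 2 alone, 0, 1 and 0 genes were called, at unadjusted counts of 636, 861 and 781, and without replicate 1 alone 10499, 10360 and 10474. The early count was 1377 without 2KR 1 h replicate 1. Apart from the untreated 2KR pair, leaving out either 2KR 1 h library raised the middle count, and leaving out any other library ended every middle call. The late count was 0 without any of the 2KR libraries at 7, 8 and 9 h, either WT 0 h library, WT 7 h or 8 h replicate 2 or WT 9 h replicate 1. It was 1 without WT 9 h replicate 2, 403 without WT 7 h replicate 1 and 440 without 2KR 4 h replicate 1. With the replicate number as a block edgeR called 0, 0 and 292, and with the block within each line 0, 0 and 0. The 35 libraries gave counts of 0, 2 and 3, at unadjusted counts of 1202, 1846 and 1649. Those few were NYNRIN (-1.24 ± 0.18) and SESN1 (-0.62 ± 0.10) in the middle window and NYNRIN (-1.11 ± 0.18), SH3TC2 (-3.65 ± 0.61) and SLC7A5, an amino acid transporter gene (-0.42 ± 0.07), late. NYNRIN, SH3TC2 and SLC7A5 were chosen after their values were seen. None of the p53 lists passed camera for a difference in any window with all libraries.

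Late against early, a contrast that holds no untreated library, showed the cell cycle genes falling in both lines. Untreated libraries still enter the estimate of spread shared by all groups. The early 2KR window also holds 2KR 1 h replicate 2, which lay nearest to the untreated 2KR replicate 1. G2 and mitosis genes fell in 27 of 30 cases in WT and 24 in 2KR (medians -0.83 and -0.73; camera adjusted p = 1.14e-37 and 2.09e-31), and G1/S genes in 21 of 30 in each line (medians -0.56 and -0.61; adjusted p = 2.38e-27 and 4.61e-31). The lowest values in WT were those of KIF20A (-1.82 ± 0.10), HMMR (-1.69 ± 0.11), E2F2 (-1.66 ± 0.12), the securin gene PTTG1 (-1.61 ± 0.10) and CDCA7 (-1.45 ± 0.22), next to RGS16, CDC20 and CDKN3. In 2KR they were those of E2F2 (-1.84 ± 0.12), CDCA7 (-1.74 ± 0.22), PTTG1 (-1.45 ± 0.10), the DNA methylation factor UHRF1 (-1.41 ± 0.07) and MCM6 (-1.34 ± 0.15), next to RGS16, ARC and WDR76. ACTA2, smooth muscle actin, rose by 1.72 ± 0.10 in WT and 1.71 ± 0.10 in 2KR. Its gene (GRCh38 chromosome 10, 88935074 to 88991339) overlaps the start of FAS (88990582 to 89015785) on the other strand. CALD1, LAMC2, a laminin chain gene, and RTL5 were among the 8 highest in both lines. ANK1 (1.95 ± 0.16), SMIM10L2A, MALL and SPATA18 completed the list in WT. In 2KR it was completed by YPEL2, the cyclin gene CCNG2 (1.48 ± 0.18), CYP1B1 and HHAT.

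Core p53 targets split between higher and lower late values. In WT 13 of 50 were higher and 9 lower late than early (18 and 12 adjusted over the list alone; camera adjusted p = 0.238), and in 2KR 15 and 4 (adjusted p = 0.00377, and adjusted p = 0.164 with an estimated correlation). FDXR was higher late in both lines (1.09 ± 0.07 and 0.95 ± 0.07), as was BAX (0.57 ± 0.10 and 0.56 ± 0.10), while PPM1D was lower (-0.60 ± 0.13 and -0.41 ± 0.13). PPM1D in 2KR was not called without any of the 2KR libraries at 2, 7, 8 and 9 h, replicate 2 at 1 h or 3 h, or WT 5 h replicate 2, nor was the list in 2KR without 2KR 1 h replicate 2 (camera adjusted p = 0.123). With the early window starting at 2 h, as in the 35 libraries, the list was lower late: 31 of 50 fell in each line, 10 and 12 rose, and the medians were -0.36 and -0.38 (camera adjusted p = 1.62e-08 and 7.68e-10, and 0.00194 and 0.00115 with an estimated correlation). CDKN1A changed there by -0.80 ± 0.04 and -0.89 ± 0.04. In WT, 11 of 16 immediate early genes fell (median -0.54; camera adjusted p = 1.08e-07, and adjusted p = 0.114 with an estimated correlation), against 4 in 2KR (adjusted p = 0.0305, and adjusted p = 0.591 with an estimated correlation). That 2KR call ended without 2KR 0 h replicate 1 or 2, 2KR 1 h replicate 1 or 2KR 3 h replicate 1 (0.144, 0.161, 0.591 and 0.0845). In WT the immediate early list had median levels of 1.54 and 1.46 at 1 h. It had 0.256 and 0.171 at 2 h, -0.243 and -0.507 at 3 h, and -0.328 to 0.373 at 7 to 9 h. The fall in WT thus rested largely on the 1 h libraries. In 2KR the 1 h levels were 1.115 in replicate 1 and -0.098 in replicate 2. Estrogen receptor targets fell in 7 of 17 cases in WT and 5 in 2KR, with 2 and 1 higher (adjusted p = 0.000164 and 0.00186, and adjusted p = 0.09 and adjusted p = 0.185 with an estimated correlation). In WT 5 of 16 interferon-stimulated genes rose, including the antiviral genes MX1 (1.34 ± 0.26) and ISG15 (0.66 ± 0.21), with camera adjusted p = 0.00842 and 0.0285 with an estimated correlation. EdgeR called 1188 genes higher and 1067 lower late in WT and 988 and 862 in 2KR, against 2153 and 2815, and 1962 and 2388, in the 35 libraries. The count of 2255 in WT became 4798 or 4833 without 2KR 0 h replicate 1 or 2, and that of 1850 in 2KR became 4191 or 4187, and 3237 without 2KR 1 h replicate 2.

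**Figure D3:**
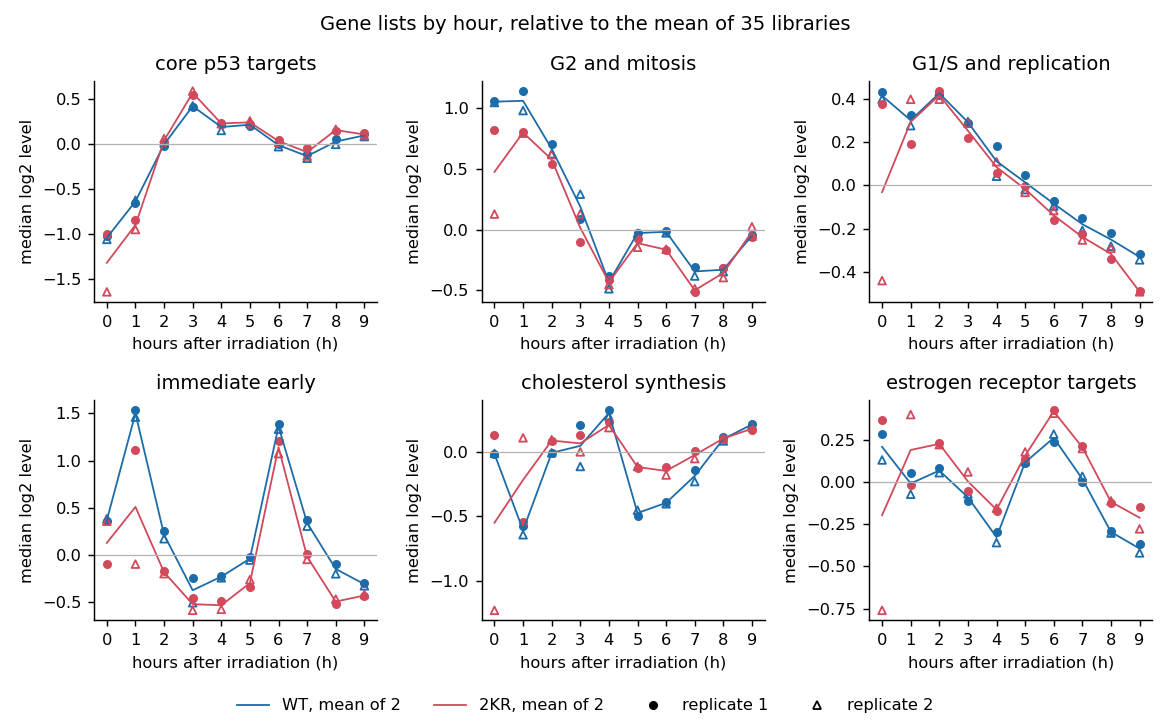
Median log2 level of the genes of 6 lists, relative to each gene's mean over the 35 libraries, by hour after irradiation in WT and 2KR, with 1 point per library. G2 and mitosis genes and G1/S genes lie lower at the last hours than at the first in both lines, with late against early medians of -0.83 and -0.56 in WT and -0.73 and -0.61 in 2KR.

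The difference between the lines in late against early had 0 genes called by edgeR, with 477 at an unadjusted p under 0.05 and a smallest adjusted p of 0.704. Common dispersion was 0.0520 with all 40 libraries and 0.0102 in the 35, so this test had a wide spread to overcome. The 0 therefore does not show that the lines change alike, nor does the 0 over any hour given below. DESeq2 and limma voom called 0, limma on log2(TPM + 1) and on log2(TPM + 0.1) called 1 each, and edgeR without a filter on low counts called 35. With all 40 libraries but 2KR 1 h replicate 1, edgeR's count was no longer 0. With the 35 libraries edgeR called 0, with 1255 at an unadjusted p under 0.05. Across the genes of at least 5 CPM called late against early in WT in the 35 libraries, 4212 of 4294 had the same sign in 2KR (r = 0.935 across genes, which are not independent replicates). For the early, middle and late responses the same sign was found in 907 of 963, 3851 of 4161 and 4006 of 4302 genes. Genes called in both lines numbered 406, 1867 and 1742 there, against 43.6, 919 and 843 for independent lists. The lines use separate untreated libraries, so these overlaps share no control. The counts of same signs and the r of 0.935 cover only genes called in WT. Over all 10853 genes of at least 5 CPM, r between the lines in the 35 libraries was 0.844 late against early. It was 0.647, 0.744 and 0.752 for the early, middle and late responses. With all 40 libraries it was 0.873 late against early, and 0.098, 0.483 and 0.464 for those responses.

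Tests over any hour ranked similar genes first in each line. In WT the 8 smallest p-values belonged to CTGF, EGR3, SESN1, INKA2, KIF20A, CDKN1A, SERPINB5 and TNFRSF10C (edgeR adjusted p from 7.77e-14 to 3.14e-12). In 2KR they belonged to CTGF, INKA2, SESN1, CDKN1A, EGR3, SERPINB5, ZNF488 and TNFRSF10C (1.92e-14 to 5.98e-12). CTGF (ENSG00000118523, GRCh38 chromosome 6, 131948176 to 131951373) stood at 414 ± 19 CPM at 6 h in WT and 263 ± 9.91 in 2KR (SD, n = 2), after 3.10 and 1.48 CPM at 5 h. EdgeR called 2530 genes in WT and 4825 in 2KR, against 7787 and 6813 in the 35 libraries. Without 2KR 0 h replicate 1 or 2 the WT count was 6403 or 6476, and the 2KR count was 12440 without replicate 1. The difference between lines over any hour had 0 genes, with 604 at an unadjusted p under 0.05, against 30 by DESeq2, 1 by limma voom and 4 by edgeR in the 35 libraries (EGR3, SESN1, SQLE and SUSD6, of which the last 2 were chosen after their values were seen). It had 6906 or 3 genes without 2KR 0 h replicate 1 or 2, and 9 without 2KR 1 h replicate 1.

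Of the 286 list tests, camera called 107, and 45 of those held with an estimated correlation. In the window responses these were the arrest, apoptosis, metabolism and core p53 lists in each line and window, the feedback list in all but the 2KR middle window, the repair list early and in the middle window in WT and in the middle window in 2KR, G2 and mitosis in all but the early 2KR window, and G1/S and estrogen receptor targets late in WT. Late against early they were G2 and mitosis and G1/S in both lines and interferon-stimulated genes in WT, and the last was the difference of the blood cell markers in late against early, 3 genes near the floor of detection. Without 2KR 0 h replicate 1, the arrest list in 2KR was not called at the fixed correlation in any window (adjusted p = 0.0559, 0.0666 and 0.052), nor the feedback list in 2KR (0.156, 0.182 and 0.145), the repair list early in 2KR (0.0575) or G2 and mitosis in 2KR (0.427, 0.171 and 0.156).

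**Figure D4:**
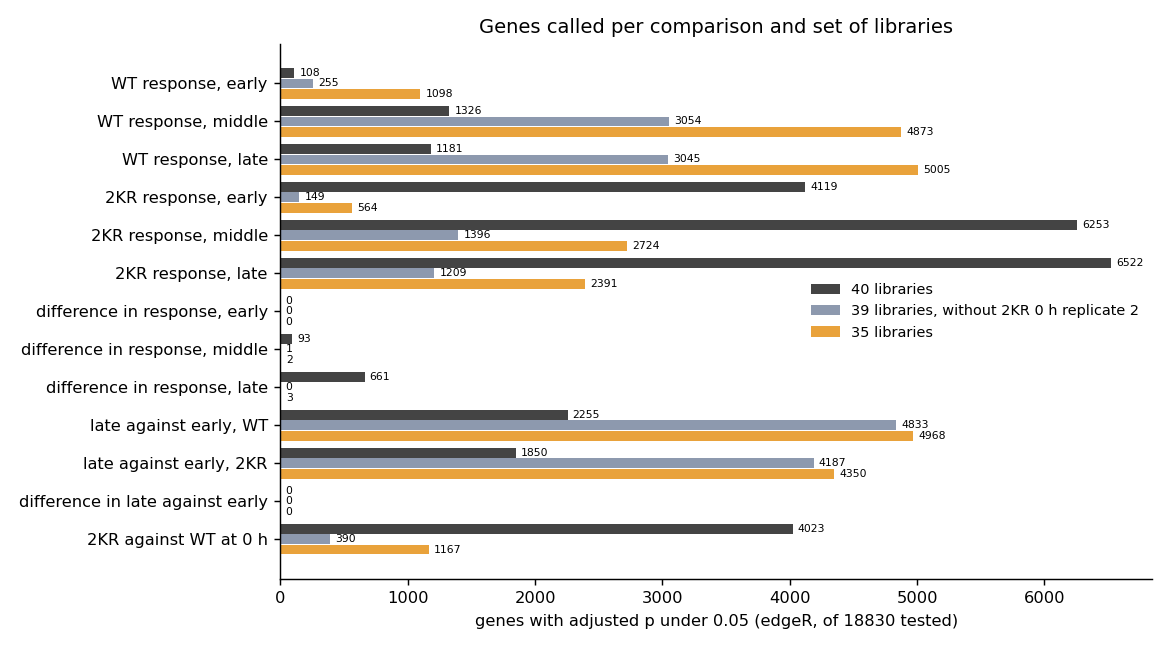
Number of genes called at an adjusted p under 0.05 in each of 13 comparisons, with all 40 libraries, with 39 (without the untreated 2KR replicate 2) and with 35 (without the 1 h libraries as well). In the late 2KR response the bars stand at 6522, 1209 and 2391 genes, and in late against early in WT at 2255, 4833 and 4968.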

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

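Apart from the random splits at the end, the results here were picked because a test of the difference between the lines called them, and all tests of explanations in this part were chosen after the results were seen. The 35-library values were also added after the data were examined.

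With all libraries, edgeR called 93 genes for a difference between lines in the middle window and 661 late. The middle window genes named by rule were RAB15 (0.62), SRGAP1 (-3.62), VPS35L (-3.32), ZNF431 (-3.08), AKAP13 (-2.98), CHD6 (-2.78), PCDHAC2 (-2.77), AAK1 (-2.48) and GNRHR2 (-2.30). Late they were SYNGAP1 (1.90), DTX4 (1.31), DHRSX (0.97), GORASP1 (0.97), SPATA7 (0.90), MOB2 (0.88), KIAA1841 (0.85), BNIP3 (0.84), MTND1P23 (-3.61), SRGAP1 (-3.49), MALAT1 (-3.42), VPS35L (-3.27), ANKRD20A11P (-3.08), FBLIM1 (-3.07), LINC00887 (-3.06) and ZNF431 (-3.03). None of these genes was called without the untreated 2KR replicate 2 or in the 35 libraries, which had 2 calls in the middle window, 3 late and 4 over any hour.

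The lists below differed between lines in each window by camera with all libraries, by medians of 0.25, 0.36 and 0.39 for G2 and mitosis genes and 0.38, 0.31 and 0.33 for G1/S genes, early, middle and late. The cholesterol list had 0.48, 0.59 and 0.42, the heat shock list 0.44, 0.52 and 0.45, the hypoxia list 0.52, 0.52 and 0.68 and the mitochondrial list -2.29, -2.16 and -2.46. None passed with an estimated correlation, with adjusted p = 0.212 to 0.575. Without the untreated 2KR replicate 2, only G2 and mitosis and heat shock in the middle window and G2 and mitosis, hypoxia and mitochondrial genes late were still called by camera. The voom medians were then -0.002 for G2 and mitosis early (adjusted p = 0.631), -0.016, -0.027 and -0.053 for G1/S, -0.023, 0.072 and -0.093 for cholesterol, 0.006 and 0.000 for hypoxia early and in the middle window, -0.246 and -0.078 for mitochondrial genes there, and 0.090 and 0.083 for heat shock early and late. G2 and mitosis early was also not called without WT 0 h replicate 2, WT 1 h replicate 2, WT 3 h replicate 1, 2KR 1 h replicate 1 or 2KR 3 h replicate 2 (adjusted p = 0.0586 to 0.119). Late against early, the differences were 0.14 for p53 arrest targets, 0.15 for G2 and mitosis, -0.39 for interferon-stimulated genes, 0.21 for immediate early genes and 0.10 for hypoxia genes, with adjusted p = 0.065 to 0.523 with an estimated correlation. The arrest list was not called without 2KR 1 h replicate 2 (voom median 0.006, adjusted p = 0.300), nor the hypoxia list without 2KR 1 h replicate 1 (0.101). The interferon list was not called without any of 10 libraries, WT 1 h replicate 1, WT 2 h replicate 2, WT 8 h replicate 2, WT 9 h replicate 1, both untreated 2KR, replicate 1 of 2KR at 1, 2 and 3 h and 2KR 9 h replicate 2 (0.0574 to 0.0921), with a voom median of -0.072 without the WT 9 h library. Immediate early genes had median levels at 1 h of 1.54 and 1.46 in WT, and of 1.115 and -0.098 in 2KR replicates 1 and 2. Their difference thus uses 1 h libraries of 2KR that differed from each other. The 3 blood cell markers differed by -1.73, with adjusted p = 0.0113 with an estimated correlation. In that list ITGAM (-2.36 ± 0.86), CD68 (-1.73 ± 1.04) and LYZ (-0.82 ± 0.34) were not called by edgeR, and their means of 1.34, 0.19 and 0.639 CPM lie near the floor. Replicates of one hour differed by as much as 0.48 and -0.43 in the list's median level (WT 5 h), and in the 35 libraries the list had adjusted p = 0.134 with an estimated correlation, so little rests on this call.

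Contrasts between hours, set after the data were examined and run in the 35 libraries, also differed between lines. For 3 and 4 h against 5 and 6 h, the differences were 0.157 for p53 apoptosis targets, 0.158 for repair targets, 0.155 for core p53 targets, -0.086 for estrogen receptor targets and -0.337 for cholesterol genes. For 8 and 9 h against 5 and 6 h they were 0.167 for repair, 0.159 for feedback and 0.136 for core p53 targets, -0.329 for cholesterol genes and 0.233 for hypoxia genes. For 6 and 7 h against 2 and 3 h they were -0.150 for repair and -0.097 for core p53 targets and 0.188 for cholesterol genes. For 8 and 9 h against 6 and 7 h they were -0.245 for cholesterol and 0.177 for hypoxia genes. These passed camera with an estimated correlation, over a family of 330 list tests. The mitochondrial list, a sign of RNA quality, also differed in the first 2 of these contrasts (-0.263 and -0.380; camera adjusted p = 0.00494 and 0.000655), but with adjusted p = 0.597 and 0.506 with an estimated correlation. Of single genes, edgeR called SQLE (-0.50), INSIG1 (-0.76), IDI1 (-0.55), HMGCS1 (-0.67), MSMO1 (-0.58) and SUSD6 (0.45) in the first of these contrasts, among 8 in all. In the second it called SQLE (-0.46), INSIG1 (-0.64), HMGCS1 (-0.61), IDI1 (-0.45), KITLG (0.39), MDM2 (0.37), P4HA1 (0.33) and SLC7A11 (0.57), among 12 in all. EdgeR called 0 genes in the third and 0 in the fourth, with 1267 and 1199 at an unadjusted p under 0.05, and no other tool was run on these contrasts. SQLE, INSIG1, IDI1, HMGCS1 and MSMO1 encode enzymes or regulators of sterol synthesis.

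The libraries behind most of these calls were weighed first. Mitochondrial genes took 31.7% of the counts in the untreated 2KR replicate 2, against 13.3% in the next highest library. Low RNA or library quality would give this, but the share is also what set the library apart, so it is no separate test. An exchange of labels between that library and 2KR 1 h replicate 2 could also account for part of the pattern. The genes that rose at 1 h in WT (median 1.37) had a median of 1.14 in the untreated replicate 2 and -0.01 in the 1 h replicate 2, both against untreated replicate 1. The first of these values lay above all of 10000 lists of random genes of like level, whose 95th percentile was 0.02. The core p53 list as a whole was lower in the untreated replicate 2 than in replicate 1 (median change -0.525, arrest targets 0.265). In WT it was higher at 1 h than at 0 h (median levels of -0.65 and -0.62, against -1.02 and -1.06). Random lists matched in level to the genes that rose at 1 h in WT had a median of -0.453 in the untreated replicate 2. No random lists were matched to the core list. How far its lower value counts against an exchange is therefore not decided. The 9 core p53 genes that rose 2-fold at 1 h in WT (median 1.397) had 0.886 in that library. They had -0.016 in 2KR 1 h replicate 2 and 1.317 in 2KR 1 h replicate 1. The 1 h replicate 2 was as near to untreated replicate 1 (r = 0.994, SD of log2 ratios 0.181) as replicates of one hour elsewhere (SD of at most 0.28), and the untreated replicate 2 was nearest to 2KR 1 h replicate 1 (r = 0.868). An exchange alone leaves the high mitochondrial share unexplained. A slower rise in the 2KR line is not decided, as the same genes had 1.47 in 2KR 1 h replicate 1, itself with 13.3% mitochondrial counts, and -0.01 in replicate 2. The labels were kept as deposited, and all 3 explanations stay open. With labels exchanged, the untreated MDM2 values of 259 and 1166 CPM would hold a library taken after irradiation.

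G2 and mitosis genes lay lower by less in 2KR than in WT late. The untreated libraries as the whole source were weighed by the difference in late against early, a contrast that holds none of them. With windows of 2 hours in the 35 libraries it had a camera adjusted p of 8.76e-11 (median 0.177). Correlation among the genes of the list could account for that small p. The adjusted p became 0.0526 with an estimated correlation, and 0.128 with all libraries. The untreated libraries as the whole source therefore stay open. The difference between the added p53 forms, and any other difference between the lines, stays open and was not tested.

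In random splits of single libraries, chosen after the results were seen, limma's late against early calls outnumbered those of every other split. This held in WT (3024 genes, 97 in the highest other split) and in 2KR (1168 and 1). It also held for 2KR against WT over hours 2 to 9 (5290 and 30). In each of these 1 of 100 splits, the real one, gave as many genes. Replicates of an hour could fall on different sides of a split, and they may be technical. The splits therefore exclude no chance difference between hours or cultures. For the difference in late against early the real split gave 0 genes, so 100 of 100 splits had to give as many and nothing is decided; the highest other split gave 44.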

How the results depend on the processing

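The 35 libraries, voom quality weights and hours 2 to 9 were added after the data were examined, and so was the choice to follow single genes only where the text names them. Counts of calls moved with the untreated 2KR libraries, and with quality weights several moved further; the causes of other shifts were not tested. DESeq2 called 175 genes early in WT, 1573, 1803 and 2044 for the difference early, middle and late, 4264, 7357 and 30 over any hour in WT, 2KR and the difference. No filter on low counts, which tests more genes, gave 218 early in WT, 2012, 1917 and 2267 for the difference, 35 for the difference in late against early, and 3855 and 1255 over any hour in WT and the difference. DESeq2's size factors in edgeR gave 373, 784 and 1025 for the difference, and a mean CPM of at least 5 gave 822 and 1011 in the middle window and late. Library totals alone gave 0 and 0 there. Windows of 2 hours gave 227 early in WT, 0 and 0 for the difference, and 908 and 888 late against early. Limma voom gave 1465 early in 2KR, 1542 at 0 h, 0 and 0 for the difference, and 2365 and 1 over any hour in 2KR and the difference.

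On log2(TPM + 1), limma called 58, 678 and 610 in WT, 7781 early in 2KR, 7691 at 0 h, 2, 0 and 2 for the difference, 1071, 905 and 1 late against early, and 1272, 1907 and 2 over any hour. On log2(TPM + 0.1) it called 58, 604 and 492 in WT, 8219 and 9538 early and middle in 2KR, 7955 at 0 h, 2, 2 and 0 for the difference, 871, 792 and 1 late against early, and 994, 1724 and 3 over any hour. Quality weights gave 249, 3268 and 3103 in WT, 17, 152 and 151 in 2KR, 23 at 0 h, 0 and 0 for the difference, 6126 late against early in WT, and 7443 and 475 over any hour. The 35 libraries gave 1098, 4873 and 5005 in WT, 564, 2724 and 2391 in 2KR, 1167 at 0 h, 2 and 3 for the difference, 4968 and 4350 late against early, and 7787 and 4 over any hour in WT and the difference. Fits of a single line gave 440, 4208, 4308, 6126 late against early and 8443 over any hour in WT, and 1717, 3488, 3626, 594 and 742 in 2KR. Hours 2 to 9 gave 7746 genes between lines.

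With the replicate block, edgeR called 0 genes in the middle window and 292 late for the difference, and with the block within each line 0 and 0, and 108 lists in each case, with no other count moved by over 1.5 times. Residuals of equal replicate numbers had a median correlation of 0.0128 over 190 pairs of groups (-0.726 to 0.349, 49 above 0.1), which gives no pairing over all groups. Within WT, replicate 2 had the higher mitochondrial share at 9 of 10 hours and replicate 1 the higher protein-coding share at all 10, so a shared origin of equal numbers in WT is not excluded. Of 107 list calls 45 held with an estimated correlation, and 58 lists passed so in the 35 libraries.

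Camera's direction turned for 18 list calls in the 35 libraries, with either correlation, 17 with windows of 2 hours there and 2 with those windows in all libraries. Medians are of limma voom values, with all libraries first, then the 35, then the 35 with windows of 2 hours where it turned there too. In 2KR early they were 0.297, -0.092 and -0.092 for G1/S, 0.536, 0.012 and 0.012 for cholesterol and -1.261, 0.091 and 0.091 for mitochondrial genes. In the 2KR middle window they were 0.510, -0.037 and -0.189 for cholesterol, 0.573, -0.060 and -0.139 for hypoxia and -1.113, 0.334 and 0.397 for mitochondrial genes. Late in 2KR they were 0.505 and -0.022 for cholesterol, 0.605 and 0.002 for hypoxia and -1.165, 0.244 and 0.225 for mitochondrial genes, and at 0 h -0.465, 0.129 and 0.129 for cholesterol. For the difference they were 0.409, -0.007 and -0.007 for G1/S and 0.646, -0.115 and -0.115 for cholesterol early, 0.330, -0.035 and -0.053 for G1/S and 0.606, -0.005 and -0.055 for hypoxia in the middle window, and 0.366, -0.060 and -0.072 for G1/S and 0.537, -0.096 and -0.131 for cholesterol late. The mitochondrial difference in the middle window (-1.524) had 0.009 with windows of 2 hours in the 35 libraries. Late against early, core p53 targets in 2KR (0.122) had -0.199 with windows of 2 hours, -0.375 in the 35 libraries and -0.213 with both. Immediate early genes in 2KR (-0.156) had -0.018 in the 35 libraries. Camera, which sets the direction, pointed against the sign of this median and of those of 0.012, 0.002 and 0.015 (hypoxia late, below). Arrest targets in the difference (0.170) had -0.051 and -0.055 with windows of 2 hours in all and in 35 libraries.

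Leaving out each library gave 53 to 256, 491 to 3054 and 432 to 3045 genes in WT, 149 to 11592, 1396 to 11827 and 1209 to 11919 in 2KR, 390 to 11410 at 0 h, and 0 to 10499, 0 to 10360 and 0 to 10474 for the difference. Late against early it gave 1512 to 4833, 1302 to 4191 and 0 to 1, over any hour 1943 to 6476, 3983 to 12440 and 0 to 6906, and 96 to 111 lists. In the 2KR windows and at 0 h, the lowest counts came without 2KR 0 h replicate 2, the highest without replicate 1. In the WT windows the lowest came without a WT 0 h library and the highest without a 2KR 0 h library. For the difference in each window the highest came without 2KR 0 h replicate 1. A lone library was then taken to vary like the other groups. Where direction turned for a list, both ends came from fits without 2KR 0 h replicate 1 or 2. Median ranges in 2KR were -0.413 to 0.184 for G2/M early, -0.090 to 0.772 and -0.655 to 0.180 for G1/S early and late, -0.108 to 1.288, -0.029 to 1.253 and -0.009 to 1.290 for cholesterol in the 3 windows, -0.051 to 1.200 and 0.015 to 1.209 for hypoxia in the middle window and late, and -2.647 to 0.197, -2.511 to 0.343 and -2.573 to 0.257 for mitochondrial genes. Cholesterol at 0 h ran from -1.265 to 0.126. Difference ranges were -0.016 to 0.790, -0.027 to 0.814 and -0.053 to 0.808 for G1/S, 0 to 1.270 for hypoxia in the middle window and -0.093 to 1.352 for cholesterol late.

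Single named genes turned in direction as follows. MCM6 late in 2KR (-0.79) had 0.037 and 0.063 on log2(TPM + 1) and log2(TPM + 0.1) and 0.33 without 2KR 0 h replicate 1, and CCNB1 in the middle window in 2KR (-0.95) had 0.093 without it. DDB2 at 0 h (0.93) had -0.09 with quality weights, -0.18 in the 35 libraries and without 2KR 0 h replicate 2, and -0.17 over hours 2 to 9. For the late difference, MALAT1 (-3.42) had 0.40, 0.74 and 0.75 with the weights, the 35 libraries and without that library, and LINC00887 (-3.06) had 0.52, 0.71 and 0.72. FBLIM1 (-3.07) had 0.067 in the 35 libraries and 0.072 without that library, where MDM2 at 0 h (1.46) had -0.004. With each library left out in turn, these ran from -1.39 to 0.33 for MCM6, -1.51 to 0.093 for CCNB1, -0.18 to 1.56 for DDB2, -0.004 to 2.17 for MDM2, -4.37 to 0.75 for MALAT1, -4.03 to 0.72 for LINC00887 and -4.005 to 0.072 for FBLIM1. Over hours 2 to 9, a comparison of irradiated libraries that does not test 0 h, DDB2 had -0.17. GADD45A, with 1.70 at 0 h, had -0.053 there. TP53 in 2KR (-0.24 in the middle window and -0.302 late) had 0.358 and 0.302 on log2(TPM + 1) and 0.361 and 0.304 on log2(TPM + 0.1). Of 203 named genes with their contrasts, all kept direction and call with DESeq2 and with its size factors, 170 did with library totals and 169 with limma voom. On log2(TPM + 1) 154 did and on log2(TPM + 0.1) 155. With quality weights 125 did, while 75 lost their call and 3 turned. Of 1114 called list members with their contrasts, 98 turned in the 35 libraries (10 of them called), 95 without 2KR 0 h replicate 2, 64 and 61 on log2(TPM + 0.1) and log2(TPM + 1), 59 with quality weights, and 0 with DESeq2, no filter, library totals, limma voom or the blocks. Of the same list members, 18 turned without 2KR 0 h replicate 1 and 8 with windows of 2 hours. The self-test recovered 86% of genes made 1.5-fold different late in 2KR and 63% in the late difference, at the spread of the 35 libraries.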

Other observations

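The contrasts between hours in this part were chosen after the data were examined and used the 35 libraries, and all tests of explanations but that with library totals were chosen after the result was seen. At 6 h against 5 and 7 h, all 16 immediate early genes were higher in both lines (medians 1.29 in WT and 1.21 in 2KR; camera adjusted p = 4.57e-97 and 7.02e-93, and 8.26e-08 in each with an estimated correlation). EGR1, a transcription factor induced within minutes of many stimuli (ENSG00000120738, GRCh38 chromosome 5, 138465490 to 138469315), rose by 2.46 and 2.30, EGR3 by 2.70 and 2.62, FOS by 1.55 and 1.13 and CTGF by 4.80 and 5.23. Other lists moved too. Medians in WT and 2KR were 0.513 and 0.376 for NF-kB targets and 0.201 and 0.108 for G2 and mitosis. Core p53 targets had -0.057 and -0.092, and p53 metabolism targets -0.13 and -0.144. Of 17 estrogen receptor targets 5 were higher in each line. EdgeR called 264 genes in WT and 292 in 2KR and 0 for the difference between lines (712 at an unadjusted p under 0.05). At 8 and 9 h against 6 and 7 h, 16 immediate early genes were lower in WT and 14 in 2KR, and 13 estrogen receptor targets were lower in each line (medians -0.55 and -0.60), GREB1 among them (-0.87 and -0.85).

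Core p53 targets fell and rose again. At 6 and 7 h against 2 and 3 h, 28 of 50 were lower and 13 higher in WT (median -0.40; camera adjusted p = 3.30e-07, and 0.00604 with an estimated correlation), and 27 and 13 in 2KR (median -0.51; 2.81e-11 and 0.000769). MDM2 changed by -1.72 and -1.93, BTG2 by -2.12 and -2.03, SESN1 by -1.73 and -1.79, PPM1D by -1.90 and -1.95 and CDKN1A by -1.22 and -1.31. The mitochondrial list, a sign of RNA quality, moved in this contrast too, by medians of 0.392 in WT and 0.286 in 2KR. At 8 and 9 h against 6 and 7 h, 19 of 50 were higher and 6 lower in WT and 23 and 4 in 2KR (medians 0.13 and 0.18; camera adjusted p = 1.02e-06 and 3.62e-13, and 0.00753 and 0.000425 with an estimated correlation). There MDM2 rose by 0.98 and 1.17, CDKN1A by 0.66 and 0.63, BTG2 by 1.14 and 0.93 and PPM1D by 1.01 and 1.02. Cholesterol synthesis genes were higher at 3 and 4 h than at 5 and 6 h in 14 of 14 cases in WT (median 0.59, adjusted p = 0.00728 with an estimated correlation) and 12 in 2KR (median 0.27, adjusted p = 0.0868 with an estimated correlation). SQLE rose from 6 and 7 h to 8 and 9 h by 0.57 in WT and 0.22 in 2KR.

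The rise of immediate early genes at 6 h was weighed against 4 technical explanations. At most 0.157% of the 10840 other genes of at least 5 CPM rose by the list's median or more in either line. A shift of all genes alike would cancel in CPM, and camera had already set the list against other genes. The percentage is therefore no separate test of such a shift. Scaling with library totals alone gave 1.19 for the lower median of both lines, against 1.20, which decides nothing because TMM factors at 5 to 7 h ran only from 0.993 to 1.03. The highest mitochondrial share at 6 h was 8.55%, against 8.78% at 5 and 7 h, which decides nothing about RNA quality. Both libraries are of the 2KR line, where the mitochondrial list moved by 0.045 at 6 h (camera adjusted p = 0.587). In WT it was higher at 6 h (0.433; adjusted p = 0.00012, and 0.446 with an estimated correlation), so RNA quality stays open. Handling shared by the cultures taken at 6 h could give the same change in both lines, and r between the lines over 264 genes was 0.95. A response of the cells at that hour would give this too, so the 2 cannot be told apart without an unirradiated culture taken at 6 h, and no biological explanation was tested.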
